A study of Homo sapiens with 18 samples.

How the data were processed

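RNA sequencing counts of 18 libraries from Raji cells were used, 3 in each of 6 groups given by GFP level (high or low) and time (24, 48 or 72 h). Per the labels, total RNA was extracted with RNeasy Plus Micro columns and made into libraries with the KAPA RNA HyperPrep kit with RiboErase, which removes ribosomal RNA and keeps RNA without a poly(A) tail. The deposited values are whole-number counts of reads per gene, summed over exons and not normalized, in 1 table whose columns per the file headers are those of the counting tool featureCounts. Per the submitters' processing notes, FastQC, STAR, featureCounts from Subread, R 4.2.1 and the genome build hg38 were used, with no role or order stated. The annotation release, the strand setting, the treatment of reads that map to several places and any read filter are not given in the sources used here.

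The names of the 18 value columns give the group and the library set, but not which of the group's 3 samples a column holds. The table has 60710 lines and 60707 genes were read; the gene ANK2, whose entry is broken over 3 lines, was left out. Symbols were found for 60506 genes, 201 have none, and gene types come from GENCODE release 29, which holds 58439 of the genes. Libraries held 27257876 to 55419458 counts in genes. Protein-coding genes took 96.65% to 97.18% of counts and ribosomal RNA genes, nuclear and mitochondrial together, 0.02% to 0.04%. Coordinates are those of the deposited table on hg38.

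Counts were fitted in R 4.3.3 with edgeR 4.0.16: filterByExpr kept 16474 genes, TMM factors scaled the libraries, and quasi-likelihood F tests were run on a model of 6 group means with 12 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all tested genes were called, in 2-sided tests. The comparisons were GFP low against high at each time and on the mean of the 3 times, the difference of that value between 72 and 24 h, an F test over the 3 times, and 48 and 72 h against 24 h within each GFP level. Fold changes are log2, with SE as the absolute log2 fold change over the square root of F. CPM are scaled by TMM. The common biological coefficient of variation was 3.5%, so that small differences pass the test.

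In total 35 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry; fry does not compare a list with other genes. The lists cover BAF subunits, B cell transcription factors, dark zone, light zone, plasma cell and memory B cell markers, targets of BCL6, MYC, NF-kB, PU.1, p53, NRF2 and AHR, B cell receptor signalling, MHC class I and II, interferon response, BCL2 family, G2 and M phase, S phase, replication histones, ribosomal proteins, nuclear and mitochondrial genes of the respiratory chain, glycolysis and hypoxia, cholesterol synthesis, unfolded protein and integrated stress responses, heat shock, immediate early genes, migration and adhesion, abundant noncoding RNAs as signs of RNA quality, and markers of T, myeloid, erythroid, and epithelial, kidney or fibroblast cells. All members were found in the table except 1 of 33 NF-kB genes. Counts of members that rose or fell use the adjustment over all genes, and are also given adjusted over the list alone where they differ.

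The groups, the tests, the gene lists, the rule for named genes and the first alternatives were fixed before the data were examined. The rule takes, for each time and for the mean, the 10 genes with the largest log2 fold change in each direction among called genes with a mean of at least 1 CPM, a symbol that is no clone, LOC, LINC or antisense name, no pseudogene type, and no overlap between the 3 and 3 libraries. For the mean, the groups had to lie on the same side at every time. It takes 5 in each direction for the other comparisons, and in each list up to 4 members in each direction by adjusted p and the member with the largest change. SMARCA4 and the BAF subunits were always taken. MIR663AHG and several small RNAs were taken by that rule. Some genes that the rule takes are not reported here. Fisher's exact test was used for overlaps between times. Other splits of the libraries were drawn over all libraries and, since the sets pair them, again within the sets, 100 at most each time.

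Libraries of a group were compared before they were averaged. The median chi-square of their counts over that expected from sampling was 1.46 to 1.7 between the unnumbered and first sets, 2.64 to 3.4 between sets 1 and 2, and 2.75 to 3.44 between the unnumbered set and set 2. All pairs differed by more than sampling noise and were kept as separate replicates. The library set, which is named in the columns and not in the sample titles, was checked for pairing. Deviations from the group means correlated at 0.22 to 0.55 for the 45 pairs of libraries from the same set (median 0.46), and at a median of -0.21 for the 90 pairs from different sets. All 18 libraries correlated best with their own set, so the sets pair the libraries, and a fit with the set as a block was run beside the fit without it.

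Alternatives were RLE size factors and upper quartile scaling, no filter beyond 1 count, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the library set as a block, and leaving out each library in turn. Added after the data had been seen were removal of trends on exon length and GC content (splines with 5 degrees of freedom per library, used as offsets), the block together with the length trend, summing the unnumbered and first libraries, leaving out library set 2, and the mean of 48 and 72 h. Plots were made with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

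The steps were tested on simulated counts for the comparison at 24 h, with 16474 genes and 200 of them changed, 50 at each fold. At folds of 1.25, 1.5, 2 and 4, edgeR recovered 24, 27, 39 and 49, with 6 unchanged genes among 145 calls. When a length trend was added, 6301 unchanged genes were called, and 27 once it was removed. The rho of fold change on length went from 0.91 to 0. The trend was added on the same exon length that the removal uses. This therefore tests the computation, and not whether exon length describes the trend in the real counts.

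Several kinds of gene are uncertain. Ribosomal protein genes, replication histones, immunoglobulin heavy chain constant regions, haemoglobin chains, mitochondrial genes with nuclear copies and small RNAs such as RN7SL1 share sequence with near-identical copies, and the counting could split or drop their reads. Overlapping and antisense genes cannot be told apart without the strand setting. Counts are in reads and not molecules, so their precision covers counting and replicate error only.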

Results

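RNA depleted of ribosomal RNA was sequenced from Raji, an established human Burkitt lymphoma B cell line. In these cells SMARCA4, also called BRG1, could be removed with an auxin-inducible degron, in which auxin lets a ubiquitin ligase mark a tagged protein for breakdown. SMARCA4 is the ATPase that drives the BAF (SWI/SNF) complexes, which move nucleosomes and open chromatin. The series asks how SMARCA4 acts in germinal centre B cells and in their tumours. Cells with high and with low GFP were profiled at 24, 48 and 72 h, with 3 libraries in each of 6 groups and 18 libraries in total. What GFP reports, how the 2 fractions were separated and from which event the hours count are not given in the sources used here; the deposited column names of 1 library set join GFP to BRG1. The differences are therefore given as GFP low against GFP high, with no statement on which fraction had lost the protein. Each library held 27257876 to 55419458 counts in genes, and 16474 genes passed the filter on low counts.

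The libraries form 3 sets, which the deposited column names give as unnumbered, 1 and 2, with 1 library of each group per set. The 6 groups were separate: 78.4% of the variance in log2 CPM, the counts scaled to the library's total, lay between groups. On the first principal component, with 43.4% of the variance, the 3 GFP low libraries at 24 h lay at 33.5 to 38.1 and the others at 7 or less. The share of counts from mitochondrial genes was 4.27% to 4.62% in GFP high and 3.48% to 3.64% in GFP low libraries at 24 h, 3.63% to 3.78% and 2.87% to 2.95% at 48 h, and 2.67% to 2.79% and 3.81% to 3.98% at 72 h. Log2 fold changes below are followed by ± SE from the fitted model, and CPM by ± SD over 3 libraries. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and a gene named for its rank in a comparison of 2 groups had no overlap between their 3 and 3 libraries. Ranks of single genes hold only among genes that the rule for named genes admits. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

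SMARCA4 mRNA itself was higher in GFP low cells at all 3 times. Its CPM was 418.3 ± 9.39 in GFP high and 589.6 ± 21.4 in GFP low cells at 24 h (n = 3), 445.8 ± 9.8 and 482.1 ± 16.2 at 48 h, and 411.2 ± 10 and 473.7 ± 14.2 at 72 h. The log2 fold changes were 0.50 ± 0.03 (adjusted p = 3.27e-12), 0.11 ± 0.03 (adjusted p = 0.00748) and 0.20 ± 0.03 (adjusted p = 2.17e-05). Within each time, every GFP low library lay above every GFP high library, and the 18 libraries spanned 405.3 to 614.2 CPM. The gene (ENSG00000127616.20, chromosome 19, 10960932 to 11079426, plus strand in hg38) encodes the protein that the degron acts on, and its mRNA does not check whether the protein was removed. With a trend on gene length removed, the value at 24 h was 0.26 (adjusted p = 3.7e-07). SMARCA2, the alternative ATPase of the same complexes, differed by 0.39 ± 0.03 at 24 h and 0.12 ± 0.03 at 48 h, and by 0.08 ± 0.03 at 72 h, where it did not pass the test. Its value at 24 h was 0.14 with the length trend removed. At 72 h it passed with the library set as a block (adjusted p = 0.02), with the length trend removed (0.022) or without the GFP low library of set 1 (0.032).

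**Figure D1:**
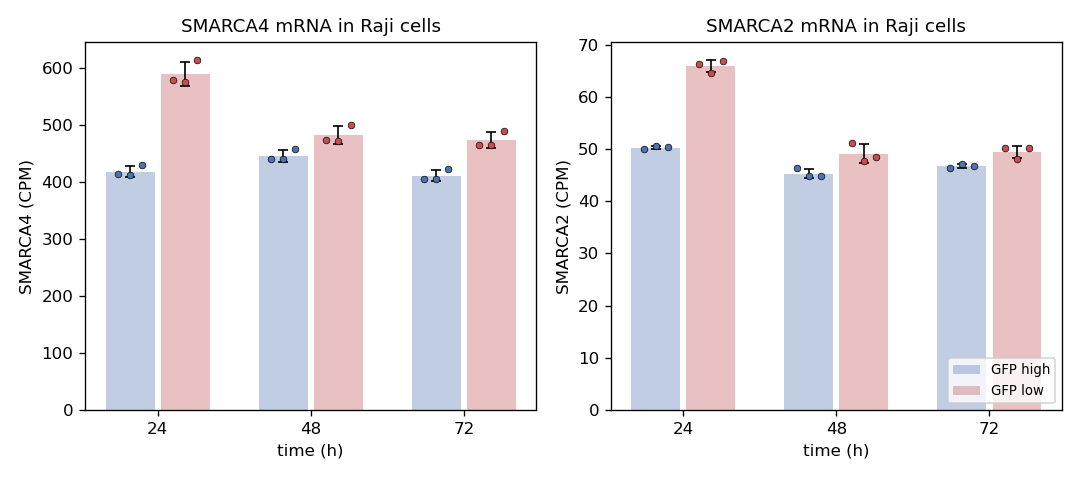
CPM of SMARCA4 (left) and SMARCA2 (right) in GFP high and GFP low Raji cells against time in hours; points are libraries, bars group means and lines SD (n = 3). SMARCA4 lies between 405.3 and 614.2 CPM, and is highest in the 3 GFP low libraries at 24 h.

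BAF subunits moved in both directions. Of 28 tested, SMARCA4 and SMARCA2 included, 15 rose and 8 fell in GFP low cells at 24 h, 6 rose and 3 fell at 48 h, and 10 rose and 5 fell at 72 h. The adaptor BICRAL rose by 0.73 ± 0.03, 0.19 ± 0.03 and 0.27 ± 0.03 at the 3 times, and the DNA-binding subunit ARID2 by 0.50 ± 0.03 at 24 h, or 0.29 with the length trend removed, and by 0.19 ± 0.03 at 48 h. The actin-related subunit ACTL6A fell, with -0.64 ± 0.03 at 24 h and -0.17 ± 0.03 at 72 h, or -0.11 at 72 h with length and GC trends removed. As a set, the subunits were higher at 24 h (camera adjusted p = 0.014, and adjusted p = 0.2 with an estimated correlation) and did not pass the test at 48 h (adjusted p = 0.44) or 72 h (adjusted p = 0.19). With a trend on gene length removed, the call at 24 h was lost (adjusted p = 0.77). Adjusted over the list alone, 16 rose and 8 fell at 24 h, 7 and 3 at 48 h, and 12 and 5 at 72 h.

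The comparison at 24 h asks what distinguished GFP low from GFP high cells at the earliest time. Among genes that the rule for named genes admits, NFATC2, a calcium-regulated transcription factor of lymphocytes, rose most. It went from 0.442 ± 0.0884 to 6.98 ± 0.605 CPM (log2 fold change 4.01 ± 0.16, adjusted p = 3.01e-15, ENSG00000101096.20, chromosome 20, 51386957 to 51562831, minus strand). CCR7, the receptor that guides lymphocytes to T cell zones, rose from 7.74 ± 0.618 to 32.7 ± 1.5 CPM (2.08 ± 0.09), and the interferon-induced antiviral gene SAMD9L from 1.7 ± 0.23 to 9.02 ± 0.773 CPM (2.39 ± 0.12). SH2D1A, the adaptor of SLAM family receptors, fell from 77.3 ± 2.6 to 19.9 ± 1.16 CPM (-1.96 ± 0.04, adjusted p = 9.38e-20). All 74 ribosomal protein genes (camera adjusted p = 1.3e-112) and all 41 replication histone genes (camera adjusted p = 4.4e-56) fell.

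Among the other genes that rose most at 24 h were IGHE, the constant region of the epsilon heavy chain (2.52 ± 0.29), DAB2IP, a Ras GTPase-activating protein (2.26 ± 0.23), KIAA1217 (2.26 ± 0.17), the large scaffold AHNAK (2.25 ± 0.15), the kinase ALPK2 (2.25 ± 0.14) and the glycine receptor subunit GLRA3 (2.16 ± 0.23). The other genes that fell most included the microtubule-binding EML1 (-2.14 ± 0.25), UBASH3A, which dampens antigen receptor signalling (-1.74 ± 0.21), the linker histone H1-5 (-1.62 ± 0.04), and the folate receptor FOLR2 (-1.61 ± 0.20). After these came the costimulatory receptor CD28 (-1.61 ± 0.22), SH3D19 (-1.60 ± 0.30), the haemoglobin chain HBD (-1.60 ± 0.16) and the ribosomal protein RPS3A (-1.55 ± 0.02). The mitochondrial ribosomal RNA MT-RNR1 also fell (-1.81 ± 0.39), but near the floor, from 0.426 ± 0.164 to 0.112 ± 0.0451 CPM. Its highest mean was in GFP high cells at 72 h (7.358 ± 0.906 CPM). SH2D1A, UBASH3A and CD28 are best known from T cells. Markers of T cells moved the same way: 5 of 7 fell, among them TRBC2 (-0.71 ± 0.05), LCK (-1.13 ± 0.09), TRAC (-1.33 ± 0.17) and CD3D (-1.46 ± 0.19), while the list did not pass camera (adjusted p = 0.07). LCK was at 13.9 ± 1.11 CPM in GFP high and 6.31 ± 0.996 in GFP low cells.

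Genes of protein synthesis and energy supply were lower in GFP low cells at 24 h. The median of the ribosomal protein genes was -0.71; examples are RPS18 -1.22 ± 0.01, RPS3A -1.55 ± 0.02 and RPL27A -0.83 ± 0.02. Of 38 nuclear genes for the respiratory chain and ATP synthase, 33 fell and 2 rose, with a median of -0.65 (camera adjusted p = 1.3e-28); examples are ATP5F1B -0.54 ± 0.02 and NDUFA4 -1.03 ± 0.03. Of the 13 genes on the mitochondrial genome, 12 fell (camera adjusted p = 3.9e-07, and adjusted p = 0.2 with an estimated correlation). Among targets of MYC, many of which serve ribosome assembly, 9 of 40 rose and 25 fell (camera adjusted p = 3.4e-07; adjusted over the list alone, 10 rose and 25 fell), with LDHA -0.84 ± 0.02, ODC1 -0.88 ± 0.02 and NPM1 -0.55 ± 0.02. Among glycolysis and hypoxia genes, 5 of 25 rose and 11 fell (camera adjusted p = 6e-04, and adjusted p = 0.17 with an estimated correlation). Examples are LDHA -0.84 ± 0.02 and PGK1 -0.79 ± 0.02. Heat shock genes, which encode chaperones, fell in 13 of 15 cases (camera adjusted p = 1.4e-06), led by HSPA8 (-0.77 ± 0.01), while the cochaperone BAG3 rose (0.93 ± 0.20).

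Proliferation genes were lower as well. Replication histone genes, whose mRNAs are made in S phase and lack a poly(A) tail, had a median of -1.02, with H1-5 -1.62 ± 0.04 and H4C2 -1.12 ± 0.03. Of 216 small nuclear, small nucleolar and Cajal body RNAs, 66 fell beside them and 8 rose, and of 6 abundant noncoding RNAs listed as signs of RNA quality 4 fell and 1 rose (camera adjusted p = 0.09). Of the G2 and M phase genes, 8 of 53 rose and 41 fell (camera adjusted p = 4.4e-12). Examples are BIRC5 -1.13 ± 0.02, CKS2 -1.40 ± 0.04 and CDK1 -0.90 ± 0.03, while MKI67 rose (0.31 ± 0.02). Of the S phase genes, 6 of 46 rose and 30 fell (camera adjusted p = 1.4e-06, and adjusted p = 0.099 with an estimated correlation), led by PCNA (-0.89 ± 0.02). Markers of centroblasts, the dividing B cells of the dark zone, went down in 14 of 20 cases and up in 4 (camera adjusted p = 1.8e-05); CCNB1 fell (-0.96 ± 0.03) and so did CD27 (-1.19 ± 0.05), while FOXO1 rose (0.53 ± 0.04).

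These group changes went along with a relation to gene length. Across 10117 protein-coding genes with a mean of at least 1 CPM, the log2 fold change at 24 h was higher for genes of greater exon length (Spearman's rho across genes 0.47), from a median of -0.74 for 126 genes of up to 1000 bp to 0.27 for 358 genes above 16000 bp. The same rho was -0.03 at 48 h and 0.05 at 72 h. The rho of the fold change on GC content was 0.1, 0.11 and 0.26 at 24, 48 and 72 h, across 10113 genes. At 72 h 4984 genes passed with length and GC trends removed, against 4345 without. Of these, 3799 were called in the same direction in both fits. With the length trend removed, 9396 genes passed the test at 24 h, of which 7660 were called in the same direction as without the correction and 95 in the opposite one. The correction used summed exon length, with a median of 3240 bp for ribosomal protein genes, against 886 bp for their annotated principal transcripts. The ribosomal protein, respiratory chain, histone, G2 and M phase, S phase, MYC target, heat shock and dark zone lists stayed past the test under that correction, with medians of -0.59, -0.49, -0.70, -0.38, -0.19, -0.19, -0.24 and -0.40. The lists of mitochondrially encoded genes (adjusted p = 0.22), memory B cell markers (0.37) and B cell transcription factors (0.081) did not. Besides SMARCA4, SMARCA2 and ARID2, given above, single values at 24 h that moved by over 1.5 times under it were those of ATP5F1B (-0.35), MKI67 (0.10), IKZF3 (0.14), MEF2C (0.18), TRBC2 (-0.38) and the chaperone HSP90B1 (0.07); with a trend on GC content removed too, that of PCNA was -0.55.

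**Figure D2:**
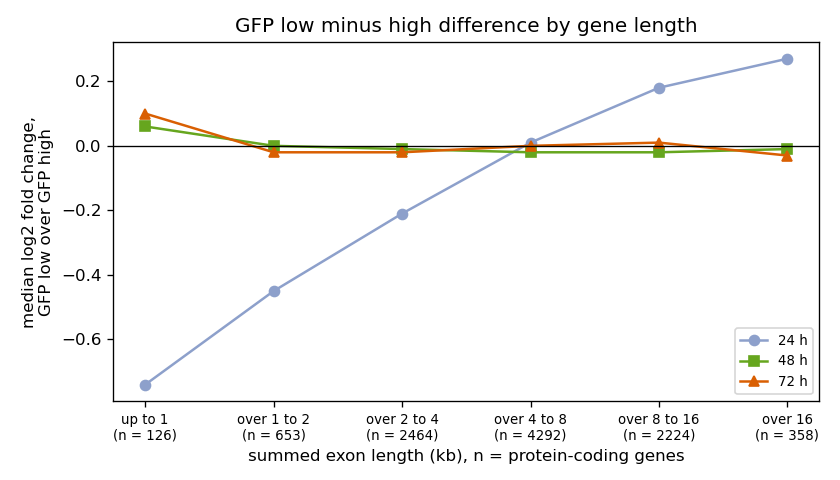
Median log2 fold change of GFP low over GFP high for protein-coding genes in 6 bins of summed exon length (kb) at 24, 48 and 72 h, each point the median over the n genes given on the axis. At 24 h the medians run from -0.74 for the shortest genes to 0.27 for the longest, and at 48 and 72 h they lie between -0.03 and 0.1.

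B cell genes went both ways at 24 h. Of 24 transcription factors of B cell identity, 17 rose and 4 fell (camera adjusted p = 0.0046, and adjusted p = 0.18 with an estimated correlation); IKZF3 (0.32 ± 0.02), MEF2C (0.38 ± 0.03) and FOXO1 were among those up and IRF8 (-0.51 ± 0.02) among those down. PRDM1, the regulator that drives plasma cell differentiation, rose from 26.2 ± 1.53 to 69.7 ± 0.314 CPM (1.41 ± 0.04), and IRF4 rose (1.07 ± 0.13), while the antibody joining chain JCHAIN fell (-1.32 ± 0.04). The plasma cell list as a whole leaned down, as 5 of 16 rose and 10 fell with a median of -0.28, and did not pass the test (camera adjusted p = 0.07). With the library set as a block it did (camera adjusted p = 0.0079), again with 5 up and 10 down. Interferon response genes were higher, as 15 of 27 rose and 2 fell (camera adjusted p = 0.0093; adjusted over the list alone, 16 rose and 2 fell), with SAMD9L 2.39 ± 0.12 and SAMD9 0.64 ± 0.07. Memory B cell markers were lower, as 4 of 12 rose and 6 fell (camera adjusted p = 0.018, and adjusted p = 0.053 with an estimated correlation), led by CR2 (-0.70 ± 0.02).

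Genes of cholesterol synthesis and of the NRF2 response to oxidants were also lower at 24 h. Of the cholesterol genes, 2 of 24 rose and 15 fell (camera adjusted p = 0.0032; adjusted over the list alone, 3 rose and 15 fell), led by INSIG1 (-0.80 ± 0.02). Of NRF2 targets, 2 of 14 rose and 9 fell (camera adjusted p = 0.00048; adjusted over the list alone, 3 rose and 9 fell). Examples are TALDO1 -0.74 ± 0.02 and NQO1 -0.81 ± 0.03. Members of other lists moved without the list passing camera. Among them were the NF-kB targets (13 rose, 15 fell), light zone centrocyte markers (8 rose, 8 fell), B cell receptor signalling (10 rose, 13 fell) and p53 targets (4 rose, 13 fell). For B cell receptor, BCL2 family, PU.1 and AHR target, light zone and erythroid lists, the median, mean and test differed in sign at 24 h. Adjusted over the list alone, the counts changed for 7 of 35 lists, by at most 2 genes.

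In total, 9531 of 16474 genes passed at 24 h, 4835 higher and 4696 lower in GFP low cells. Of these, 519 were at least 2-fold higher and 400 at least 2-fold lower, and the median absolute log2 change of the called genes was 0.40. With the length trend removed, 863 genes were at least 2-fold higher and 175 at least 2-fold lower. Of 35 lists, 16 passed camera, and 10 did with an estimated correlation.

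The comparison at 48 h asks which differences held or appeared by the second time. Among genes that the rule for named genes admits, NFATC2 again rose most, from 0.495 ± 0.109 to 3.2 ± 0.284 CPM (2.69 ± 0.16, adjusted p = 6.17e-11). LTB, the lymphotoxin beta chain that B cells use to organise lymphoid tissue, fell from 35.9 ± 1.94 to 13.4 ± 0.968 CPM (-1.42 ± 0.06, adjusted p = 1.54e-13; ENSG00000227507.3, chromosome 6, 31580525 to 31582522, minus strand). HRK, a cell death activator of the BCL2 family, rose from 1.61 ± 0.127 to 5 ± 0.28 CPM (1.64 ± 0.13). All 13 mitochondrially encoded genes fell (camera adjusted p = 5.7e-29), as did 40 of 53 genes of G2 and M phase (camera adjusted p = 1.9e-15), while 11 of 23 targets of the repressor BCL6 rose (camera adjusted p = 7e-09).

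Other genes that rose most at 48 h were DAB2IP (2.26 ± 0.19), SAMD9L (1.93 ± 0.14), GLRA3 (1.89 ± 0.18), CPLX1, a regulator of vesicle release (1.84 ± 0.21), MLC1 (1.74 ± 0.18), THEMIS2, an adaptor of B cell receptor signalling (1.73 ± 0.08), IGHE (1.70 ± 0.29) and the selectin ligand SELPLG (1.42 ± 0.18). Those that fell most were CD28 (-1.90 ± 0.21), ATRN (-1.73 ± 0.20), the sialic acid receptor CD33 (-1.50 ± 0.15), the adhesion molecule NRCAM (-1.46 ± 0.18), the secreted nuclease DNASE1L3 (-1.43 ± 0.18), TTC24 (-1.43 ± 0.22), the transporter ABCA6 (-1.40 ± 0.11) and MARCHF1, a ubiquitin ligase that removes MHC class II from the surface (-1.39 ± 0.12). CD28 lay at 2.43 ± 0.143 CPM in GFP high and 0.651 ± 0.153 in GFP low cells; of 7 T cell markers, 2 fell beside it (camera adjusted p = 0.22).

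Signalling genes of the light zone were lower at 48 h. Of NF-kB targets, 7 of 30 rose and 14 fell (camera adjusted p = 2.6e-07; adjusted over the list alone, 7 rose and 16 fell), led by LTB, its partner LTA (-1.01 ± 0.05), CD83 (-0.33 ± 0.02) and TNF (-0.98 ± 0.07), while CCR7 rose (1.15 ± 0.10). Of light zone markers, 2 of 19 rose and 13 fell (camera adjusted p = 2.6e-07, and adjusted p = 0.052 with an estimated correlation; adjusted over the list alone, 2 rose and 14 fell), with CD83 -0.33 ± 0.02, SEMA7A -0.72 ± 0.06 and CD40 -0.40 ± 0.04. Of B cell receptor signalling genes, 4 of 26 rose and 14 fell (camera adjusted p = 6.2e-11; adjusted over the list alone, 5 rose and 14 fell). Examples are CR2 -0.80 ± 0.02 and CD22 -0.40 ± 0.02, with the inhibitory Fc receptor FCGR2B at -0.97 ± 0.07. Of memory B cell markers, 2 of 12 rose and 6 fell (camera adjusted p = 0.00015; adjusted over the list alone, 2 rose and 7 fell), with CR2 -0.80 ± 0.02 and BANK1 -0.29 ± 0.03, while GPR183, a receptor for oxysterols, rose (1.20 ± 0.08). Of MHC class I genes, 1 of 17 rose and 10 fell (camera adjusted p = 0.00024, and adjusted p = 0.076 with an estimated correlation; adjusted over the list alone, 1 rose and 11 fell), led by B2M (-0.26 ± 0.02). Of PU.1 targets, 3 of 24 rose and 9 fell (camera adjusted p = 0.011, and adjusted p = 0.052 with an estimated correlation; adjusted over the list alone, 7 rose and 9 fell); the test pointed down, the median was 0.01 and the mean -0.01, and the call was lost with the length trend removed (adjusted p = 0.22).

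Targets that BCL6 represses in germinal centre B cells were higher, and 4 of 23 fell. PRDM1 rose (1.34 ± 0.04), as did CXCR4, the receptor that holds cells in the dark zone (0.54 ± 0.03), and GPR183, while the cell cycle inhibitor CDKN1A fell (-0.55 ± 0.05). Of BCL2 family genes, 7 of 15 rose and 3 fell (camera adjusted p = 5.9e-06; adjusted over the list alone, 9 rose and 3 fell); death activators BCL2L11 (0.33 ± 0.02), BMF (0.70 ± 0.05) and HRK rose along with the survival gene BCL2 (0.62 ± 0.04), and the survival gene MCL1 fell (-0.23 ± 0.02). Plasma cell genes were higher, as 6 of 16 rose and 1 fell (camera adjusted p = 0.014). Examples are PRDM1 1.34 ± 0.04 and DERL3 0.70 ± 0.08 up and CD38 down (-1.12 ± 0.04). That list's call was lost with length and GC trends removed (adjusted p = 0.062).

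Genes of G2 and M phase had a median of -0.17 and, adjusted over the list alone, 1 rose and 42 fell, with LBR -0.33 ± 0.02, CDK1 -0.29 ± 0.03 and CKS2 -0.37 ± 0.04. Replication histones went the other way from 24 h: 31 of 41 rose (camera adjusted p = 6.8e-19, and adjusted p = 0.072 with an estimated correlation). Examples are H2BC11 0.60 ± 0.03 and H4C3 0.66 ± 0.04. The median of the mitochondrially encoded genes was -0.42. Of 216 small nuclear, small nucleolar and Cajal body RNAs, 30 fell and 6 rose. Abundant noncoding RNAs listed as signs of RNA quality moved down as the mitochondrially encoded genes did, and against the histones. Of 6, 1 rose and 4 fell (camera adjusted p = 8.6e-06). SNHG1 fell (-0.53 ± 0.03) and RN7SL1, the RNA of the signal recognition particle, rose (1.00 ± 0.13). Of cholesterol synthesis genes, 2 of 24 rose and 14 fell (camera adjusted p = 3e-05; adjusted over the list alone, 3 rose and 15 fell), led by INSIG1 (-0.42 ± 0.02).

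Of heat shock genes, 1 of 15 rose and 9 fell (camera adjusted p = 0.014, and adjusted p = 0.12 with an estimated correlation; adjusted over the list alone, 1 rose and 10 fell). Of MYC targets, 1 of 40 rose and 14 fell (camera adjusted p = 0.019, and adjusted p = 0.076 with an estimated correlation; adjusted over the list alone, 1 rose and 15 fell). The heat shock call was lost without the GFP low library of set 2 (adjusted p = 0.053). The MYC call was lost without the GFP high library of set 2 (adjusted p = 0.072), the GFP low library of set 1 (0.051) or all of set 2 (0.061), and both calls were lost with a stricter filter (0.1 for MYC and 0.06 for heat shock). Ribosomal protein (2 rose, 14 fell), nuclear respiratory chain (3 and 4), S phase (9 and 7), dark zone (5 and 13) and interferon genes (8 and 3) did not pass as lists, though the dark zone list did with the length trend removed (adjusted p = 0.027). For the AHR target, unfolded protein response, glycolysis, S phase, respiratory chain and B cell transcription factor lists, none past camera at 48 h, the median, mean and test differed in sign. For 18 of 35 lists the counts changed when adjusted over the list alone, by at most 4 genes.

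At 48 h 3926 genes passed the test, 1749 higher and 2177 lower in GFP low cells, with 192 and 75 of them changed at least 2-fold. The majority turned with upper quartile scaling, where 52.8% of calls were higher in place of 44.5%. The median absolute log2 change of the called genes was 0.22. Of 35 lists, 16 passed camera and 10 did with an estimated correlation.

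The comparison at 72 h asks the same question at the last time. Targets of NF-kB and markers of light zone centrocytes, the germinal centre B cells that are selected by antigen and T cell help, were lower in GFP low cells, where 22 of 30 (camera adjusted p = 2.8e-33) and 16 of 19 (camera adjusted p = 8.9e-32) fell. LTB fell from 41 ± 1.61 to 14.9 ± 0.957 CPM (-1.46 ± 0.06, adjusted p = 8.04e-14), CD83, an activation marker of the light zone, from 224.2 ± 1.34 to 123 ± 1.14 CPM (-0.87 ± 0.02, adjusted p = 4.07e-18), and the receptor CD40 from 63.7 ± 0.877 to 38.8 ± 0.521 CPM (-0.72 ± 0.04). Among genes that the rule for named genes admits, DAB2IP rose most, from 0.605 ± 0.117 to 4.1 ± 0.722 CPM (2.72 ± 0.18, adjusted p = 2e-10, ENSG00000136848.17, chromosome 9, 121567057 to 121785530, plus strand). Of replication histones, all of which fell at 24 h, 39 of 41 rose at 72 h (camera adjusted p = 7.7e-63).

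Other genes that rose most at 72 h were NFATC2 (2.64 ± 0.17), IGHE (2.07 ± 0.34), MLC1 (1.92 ± 0.17), CPLX1 (1.84 ± 0.21), GLRA3 (1.66 ± 0.19), HRK (1.65 ± 0.12), the DNA-binding protein ARID3B (1.52 ± 0.13) and RAB27B, a GTPase of secretory vesicles (1.52 ± 0.04). The mitochondrial ribosomal RNAs MT-RNR1 (-5.69 ± 0.27) and MT-RNR2 (-5.90 ± 0.28) headed the genes that fell. Their counts are what ribosomal RNA depletion left: MT-RNR2 was at 12.1 ± 1.78 CPM in GFP high cells at 72 h and below 1 CPM in the other 5 groups. After them came CD28 (-2.21 ± 0.21), ATRN (-2.02 ± 0.18), MARCHF1 (-1.78 ± 0.14), the somatostatin receptor SSTR3 (-1.71 ± 0.18), DNASE1L3 (-1.71 ± 0.18), ABCA6 (-1.67 ± 0.12) and NRCAM (-1.54 ± 0.23). Beside CD28, T cell markers were lower as a list, as 5 of 7 fell (camera adjusted p = 0.0059; adjusted over the list alone, 6 fell), with LCK at -0.70 ± 0.08.

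The median of NF-kB targets was -0.28 and 3 rose; 5 members fell at least 2-fold, and examples are CD83 -0.87 ± 0.02, LTA -1.33 ± 0.05, LTB -1.46 ± 0.06 and FAS -0.72 ± 0.04. The median of light zone markers was -0.40 and 1 rose, with CD83 -0.87 ± 0.02, SLAMF1 -0.76 ± 0.04, CD40 -0.72 ± 0.04 and TRAF1 -0.59 ± 0.04. The survival gene BCL2A1, which stands in both lists, fell by 1.17 ± 0.08, and MYC, also a light zone marker, rose (0.24 ± 0.04). Of B cell receptor signalling genes, 5 of 26 rose and 14 fell (camera adjusted p = 9.7e-13; adjusted over the list alone, 5 rose and 15 fell), with the complement receptor CR2 (-0.98 ± 0.02), MS4A1, a B cell surface protein (-0.48 ± 0.03), and PRKCB (-0.31 ± 0.02). Of memory B cell markers, 1 of 12 rose and 6 fell (camera adjusted p = 1.9e-08; adjusted over the list alone, 2 rose and 7 fell), with CR2 -0.98 ± 0.02 and BANK1 -0.48 ± 0.03.

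Antigen presentation genes were lower. Of MHC class I genes, 14 of 17 fell (camera adjusted p = 5e-08), led by HLA-B (-0.42 ± 0.03), CALR (-0.17 ± 0.02) and the peptide transporter TAP1 (-0.41 ± 0.05). Of MHC class II genes, 2 of 16 rose and 10 fell (camera adjusted p = 1.8e-06, and adjusted p = 0.093 with an estimated correlation), led by HLA-DRA (-0.37 ± 0.02). Of PU.1 targets, 2 of 24 rose and 9 fell (camera adjusted p = 0.002; adjusted over the list alone, 4 rose and 9 fell); the median was 0.03, the mean -0.08 and the test pointed down, with the call lost once the length trend was removed (adjusted p = 0.084).

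BCL6 targets were higher at 72 h, as 10 of 23 rose and 5 fell (camera adjusted p = 0.00034). PRDM1 (1.47 ± 0.04), CXCR4 (0.62 ± 0.03) and SUB1 (0.44 ± 0.03) rose, and CDKN1A (-0.75 ± 0.05) and CD80 (-0.53 ± 0.04) fell. Of B cell transcription factors, 13 of 24 rose and 4 fell (camera adjusted p = 0.00068, and adjusted p = 0.12 with an estimated correlation; adjusted over the list alone, 14 rose and 4 fell), with BCL6 itself up (0.36 ± 0.02) along with FOXO1 (0.60 ± 0.04) and ID3 (0.93 ± 0.07). Of BCL2 family genes, 7 of 15 rose and 3 fell (camera adjusted p = 0.0031, and adjusted p = 0.13 with an estimated correlation). Examples are BCL2L11 0.33 ± 0.02, HRK 1.65 ± 0.12 and BMF 0.55 ± 0.05; with length and GC trends removed, that call was lost too (adjusted p = 0.13).

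Replication histones had a median of 0.47, with H2BC11 0.81 ± 0.03, H3C12 0.79 ± 0.04 and H4C3 0.74 ± 0.04. The mitochondrially encoded genes were higher as well, as 12 of 13 rose (camera adjusted p = 2.2e-42). Examples are MT-CO2 0.59 ± 0.02 and MT-CO1 0.50 ± 0.03. Abundant noncoding RNAs moved with both groups: 4 of 6 rose (camera adjusted p = 2.5e-21), NEAT1 from 297.1 ± 4.16 to 624.6 ± 4.2 CPM and RN7SL1 from 1563 ± 219 to 3894 ± 62.2 CPM. Of 216 small nuclear, small nucleolar and Cajal body RNAs, 46 rose and 3 fell. Of G2 and M phase genes, 1 of 53 rose and 31 fell (camera adjusted p = 3e-10; adjusted over the list alone, 1 rose and 34 fell), with HMMR -0.37 ± 0.03, CDK1 -0.32 ± 0.03 and TOP2A -0.28 ± 0.03. Of cholesterol synthesis genes, 2 of 24 rose and 13 fell (camera adjusted p = 9e-08). Examples are INSIG1 -0.46 ± 0.02 and FDFT1 -0.29 ± 0.02.

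Ribosomal protein (13 rose, 15 fell), nuclear respiratory chain (5 and 3), S phase (9 and 11), dark zone (3 and 12), plasma cell (5 and 3), interferon (5 and 3) and p53 target genes (5 and 5) did not pass as lists at 72 h. With the library set as a block, the dark zone (adjusted p = 0.023), heat shock (0.01) and NRF2 lists (0.024) did, and with the length trend removed they did as well (adjusted p = 0.039, 0.042 and 0.045). The median, mean and test also differed in sign for the S phase, glycolysis, respiratory chain, migration and unfolded protein response lists at 72 h. For 16 of 35 lists the counts changed when adjusted over the list alone, by at most 4 genes.

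At 72 h 4345 genes passed the test, 2123 higher and 2222 lower in GFP low cells, with 166 and 152 of them changed at least 2-fold and a median absolute log2 change of 0.21. Of 35 lists, 16 passed camera, and 13 did with an estimated correlation.

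**Figure D3:**
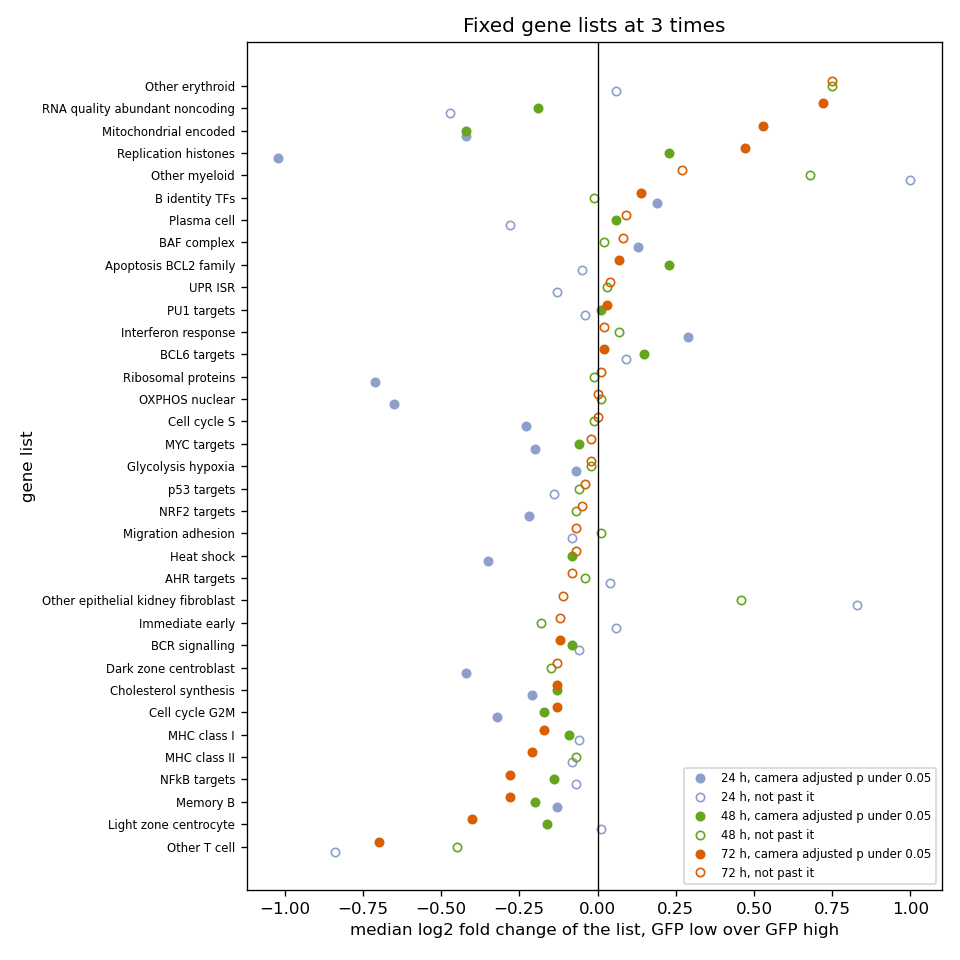
Median log2 fold change of GFP low over GFP high for each of 35 gene lists at 24, 48 and 72 h; filled points passed camera at an adjusted p under 0.05 and open points did not. Replication histones move from -1.02 at 24 h to 0.47 at 72 h, and light zone markers reach -0.40 at 72 h.

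A difference on the mean over the 3 times need not hold at each time. Among genes that the rule for named genes admits, NFATC2 had the highest mean difference (3.12 ± 0.09, adjusted p = 7.53e-17). It was followed by DAB2IP (2.41 ± 0.12), IGHE (2.10 ± 0.18), GLRA3 (1.90 ± 0.12), SAMD9L (1.90 ± 0.08), CPLX1 (1.71 ± 0.12), KIAA1217 (1.64 ± 0.10), HRK (1.55 ± 0.07), RAB27B (1.54 ± 0.03) and THEMIS2 (1.52 ± 0.05). Beside the mitochondrial ribosomal RNAs MT-RNR1 (-2.65 ± 0.32) and MT-RNR2 (-2.53 ± 0.27), the lowest were CD28 (-1.91 ± 0.12), DNASE1L3 (-1.47 ± 0.10), EML1 (-1.44 ± 0.13), LTB (-1.32 ± 0.03), SPATA48 (-1.30 ± 0.06), CD33 (-1.30 ± 0.09), UBASH3A (-1.30 ± 0.12) and ABCA6 (-1.29 ± 0.07). The means of MT-RNR1 and MT-RNR2 rest mainly on GFP high cells at 72 h, and at 48 h neither passed the test (-0.45 ± 0.64 and -0.30 ± 0.55). RAB27B ran from 11.9 ± 0.441, 14.3 ± 0.397 and 17.2 ± 1.08 CPM in GFP high cells at the 3 times to 38.9 ± 0.683, 37.3 ± 0.709 and 49.1 ± 1.53 in GFP low cells.

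**Figure D4:**
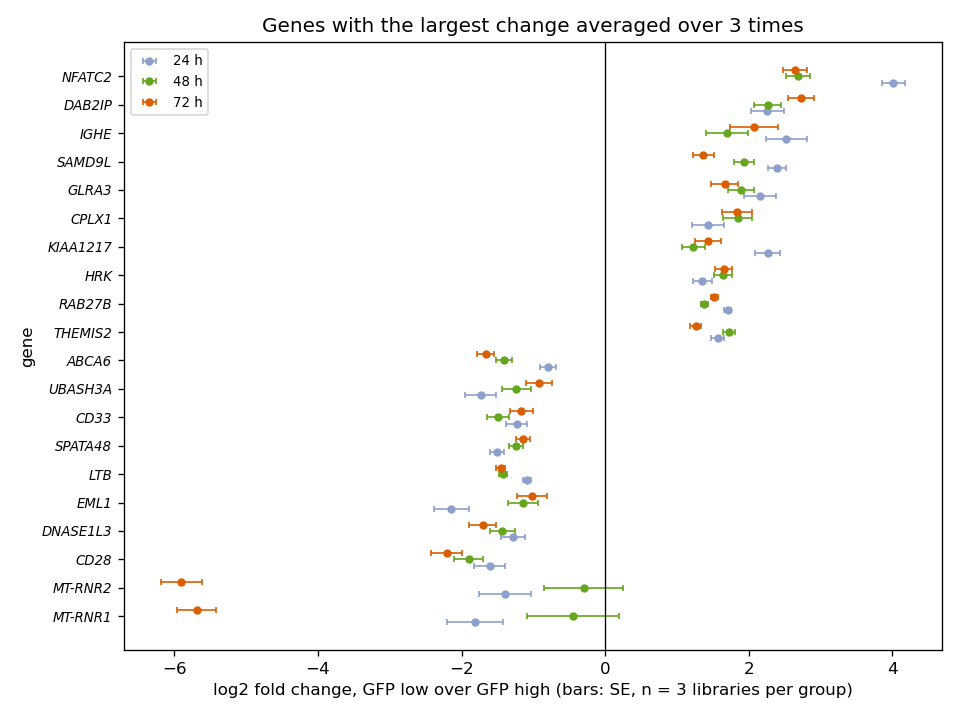
Log2 fold change of GFP low over GFP high at 24, 48 and 72 h for the 10 genes highest and the 10 lowest on the mean over times, among genes that the rule for named genes admits. Points are estimates and bars SE (n = 3 libraries per group). NFATC2 lies between 2.64 and 4.01 and CD28 between -2.21 and -1.61 over the 3 times, and MT-RNR2 lies at -5.90 at 72 h.

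On the mean over times, lists for growth and proliferation were lower in GFP low cells. All 74 ribosomal protein genes fell (camera adjusted p = 7.5e-54), and of nuclear respiratory chain genes 2 of 38 rose and 32 fell (camera adjusted p = 2e-13; adjusted over the list alone, 3 rose and 32 fell); both lists passed camera at 24 h and not at 48 or 72 h. Of G2 and M phase genes, 3 of 53 rose and 45 fell (camera adjusted p = 3.3e-19), with BIRC5 -0.41 ± 0.01, CDK1 -0.50 ± 0.02 and LBR -0.38 ± 0.01. Of MYC targets, 5 of 40 rose and 24 fell (camera adjusted p = 4.7e-06; adjusted over the list alone, 6 rose and 24 fell), led by ODC1, the first enzyme of polyamine synthesis (-0.39 ± 0.01). Of heat shock genes, 1 of 15 rose and 14 fell (camera adjusted p = 4.7e-06). Of cholesterol synthesis genes, 3 of 24 rose and 17 fell (camera adjusted p = 1.6e-06; adjusted over the list alone, 4 rose and 18 fell), led by INSIG1 (-0.56 ± 0.01). Of NRF2 targets, 2 of 14 rose and 6 fell (camera adjusted p = 0.0012), and of dark zone markers, 3 of 20 rose and 14 fell (camera adjusted p = 0.00016).

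Immune signalling lists were lower on the mean too. Of NF-kB targets, 8 of 30 rose and 19 fell (camera adjusted p = 4.4e-07). Examples are CD83 -0.55 ± 0.01 and LTA -0.98 ± 0.03. Of light zone markers, 4 of 19 rose and 14 fell (camera adjusted p = 5.1e-07). Neither list passed at 24 h. Of B cell receptor genes, 7 of 26 rose and 12 fell (camera adjusted p = 4e-04; adjusted over the list alone, 7 rose and 13 fell). Of memory B cell markers, 2 of 12 rose and 6 fell (camera adjusted p = 8.7e-06; adjusted over the list alone, 3 rose and 7 fell). CR2 (-0.83 ± 0.01) was lower throughout. BCL6 targets were higher, as 13 of 23 rose and 7 fell (camera adjusted p = 0.00016), with PRDM1 1.41 ± 0.02, CXCR4 0.43 ± 0.02 and BCL2 0.56 ± 0.03. Interferon genes were higher, as 12 of 27 rose and 2 fell (camera adjusted p = 0.022). The list passed at 24 h only. With the length trend removed, the calls of the BCL6 target (adjusted p = 0.057) and memory B cell lists (adjusted p = 0.053) were lost.

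The other lists past camera on the mean were lost with an estimated correlation. Of BCL2 family genes, 7 of 15 rose and 3 fell (camera adjusted p = 0.0061, and adjusted p = 0.14 with an estimated correlation; adjusted over the list alone, 7 rose and 4 fell). Of B cell transcription factors, 16 of 24 rose and 5 fell (camera adjusted p = 0.00084, and adjusted p = 0.12 with an estimated correlation; adjusted over the list alone, 17 rose and 5 fell). Of S phase genes, 7 of 46 rose and 27 fell (camera adjusted p = 0.001, and adjusted p = 0.19 with an estimated correlation; adjusted over the list alone, 7 rose and 28 fell). Of MHC class I genes, 11 of 17 fell (camera adjusted p = 0.00024, and adjusted p = 0.071 with an estimated correlation). Of MHC class II genes, 4 of 16 rose and 10 fell (camera adjusted p = 0.028, and adjusted p = 0.42 with an estimated correlation). Among T cell markers, 6 of 7 fell (camera adjusted p = 0.0098, and adjusted p = 0.051 with an estimated correlation). Among glycolysis genes, 4 of 25 rose and 11 fell (camera adjusted p = 0.024, and adjusted p = 0.34 with an estimated correlation). Among BAF subunits, 15 of 28 rose and 7 fell (camera adjusted p = 0.014, and adjusted p = 0.21 with an estimated correlation; adjusted over the list alone, 16 rose and 7 fell). Among replication histones, 6 of 41 rose and 30 fell (camera adjusted p = 0.0015, and adjusted p = 0.48 with an estimated correlation). Among mitochondrially encoded genes, 12 of 13 fell (camera adjusted p = 0.011, and adjusted p = 0.48 with an estimated correlation). Replication histones fell on the mean although they rose at 48 and 72 h. With the length trend removed, the mean calls of BCL2 family genes (adjusted p = 0.057), BAF subunits (0.36), MHC class II genes (0.18), replication histones (0.67) and mitochondrially encoded genes (0.77) were lost. Without the GFP high library of set 2 at 48 h, those of glycolysis genes (adjusted p = 0.054) and MHC class II genes (adjusted p = 0.057) were lost. Both calls were also lost with a stricter filter (0.063 and 0.08), that of glycolysis genes with the unnumbered and set 1 libraries summed (0.059) and that of MHC class II genes without library set 2 (0.089). The median of glycolysis genes turned from -0.01 to 0.02 with upper quartile scaling, and was -0.06 with the length trend removed. The p53 target list did not pass (adjusted p = 0.057) but did with the library set as a block (adjusted p = 0.043).

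Over the mean of the 3 times, 8550 genes passed the test, 4119 higher and 4431 lower, with 162 and 81 of them changed at least 2-fold. With upper quartile scaling 56.5% of calls on the mean were higher in place of 48.2%. Over 48 and 72 h alone, 5361 genes passed, of which 4258 were called in the same direction as on the mean of 3 times and 238 in the opposite one. There the value was -0.04 for BIRC5, -0.30 for CDK1 and -0.15 for ODC1. Of lists not past camera on the mean, those of plasma cell, immediate early, migration, AHR target and unfolded protein response genes had a median, mean and test that differed in sign. For 12 of 35 lists the counts changed when adjusted over the list alone, by at most 4 genes.

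The overlap between times asks whether the same genes differed. At all 3 times, 685 genes were higher in GFP low cells and 702 lower, and 47 and 19 of them were changed at least 2-fold each time. NFATC2, DAB2IP, IGHE, GLRA3, SAMD9L, CPLX1, KIAA1217, HRK, RAB27B, THEMIS2 and PRDM1 belong to the 47, and CD28, DNASE1L3, EML1, LTB, SPATA48 and CD33 to the 19. Between 48 and 72 h, 933 genes were higher at both against 225 expected from independent lists (Fisher's exact test p = 0 at the computer's precision), and 1040 lower against 294. Between 24 and 72 h the shared numbers were 1316 against 623 higher (Fisher's exact p = 1.5e-248) and 1377 against 633 lower (p = 4.6e-278). Between 24 and 48 h they were 1066 against 513 higher (Fisher's exact p = 7.1e-187) and 1145 against 621 lower (p = 1.1e-143). With the library set as a block, the shared lower genes numbered 1731 between 24 and 48 h and 1601 between 48 and 72 h. Genes are not independent, so these p-values overstate the evidence.

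Of the genes called at 48 and at 72 h, 1973 of 2187 (90.2%) had the same direction. The share was 72.6% (2211 of 3044) between 24 and 48 h and 79% (2693 of 3411) between 24 and 72 h. Pearson's r of the log2 fold changes across 12148 genes with a mean of at least 1 CPM was 0.58 between 48 and 72 h, 0.40 between 24 and 48 h and 0.35 between 24 and 72 h (Spearman's rho 0.45, 0.28 and 0.36). The comparisons at the 3 times share no library.

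The difference between 24 and 72 h in the GFP low minus GFP high value shows what changed with time. All 41 replication histones (camera adjusted p = 7.7e-139) and all 74 ribosomal protein genes (camera adjusted p = 1.4e-130) moved up between the times, and 22 of 30 NF-kB targets moved down (camera adjusted p = 8.8e-08). HBD, the delta chain of haemoglobin, moved most upward (2.75 ± 0.23, adjusted p = 2.14e-09), as it went from 3.19 ± 0.0846 CPM at 24 h to 1.06 ± 0.283 at 72 h in GFP high cells and from 1.07 ± 0.192 to 2.33 ± 0.204 in GFP low cells. Small noncoding RNAs that share sequence with other copies in the genome made up the other upward ranks: RNU6ATAC (2.64 ± 0.35), RN7SKP203 (2.18 ± 0.43), RN7SL1 (2.12 ± 0.18) and RN7SKP71 (2.07 ± 0.46). ATRN (-2.02 ± 0.26) and ALPK2 (-1.92 ± 0.22) moved down after MT-RNR2 (-4.51 ± 0.55), MT-RNR1 (-3.87 ± 0.61) and MIR663AHG (-3.81 ± 1.16). MIR663AHG rests on 1 library: without the unnumbered GFP low library at 24 h its value was -0.81 (adjusted p = 0.068), and with limma-voom it was -2.13 (adjusted p = 0.24).

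Here rose and fell stand for a higher or lower GFP low minus GFP high value at 72 h than at 24 h. The median difference was 1.54 for replication histones and 0.70 for ribosomal protein genes. With the length trend removed it was 0.63 in place of 0.98 for mitochondrially encoded genes, 0.27 in place of 0.42 for dark zone markers and -0.08 in place of -0.19 for B cell receptor genes, each still past camera. Of nuclear respiratory chain genes 34 of 38 rose (camera adjusted p = 1.8e-33), and of mitochondrially encoded genes 12 of 13 rose (camera adjusted p = 4e-33). Of MYC targets 23 of 40 rose and 4 fell (camera adjusted p = 1.3e-06; adjusted over the list alone, 24 rose and 4 fell). Of dark zone markers 13 of 20 rose and 2 fell (camera adjusted p = 8.4e-05). Among heat shock genes 10 of 15 rose (camera adjusted p = 3.4e-05), and of plasma cell genes 9 of 16 rose and 3 fell (camera adjusted p = 0.0015). Abundant noncoding RNAs moved with them, as 4 of 6 rose (camera adjusted p = 2.9e-10).

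In the other direction, NF-kB targets had a median of -0.42 and, adjusted over the list alone, 2 rose and 23 fell. Of light zone markers 15 of 19 fell (camera adjusted p = 1.9e-07; adjusted over the list alone, 1 rose and 16 fell). Of B cell receptor genes 4 of 26 rose and 15 fell (camera adjusted p = 0.00011; adjusted over the list alone, 4 rose and 16 fell), and of interferon genes 1 of 27 rose and 10 fell (camera adjusted p = 0.012). Calls lost with an estimated correlation were those for G2 and M phase genes, of which 28 of 53 rose and 10 fell (camera adjusted p = 1e-05, and adjusted p = 0.093 with an estimated correlation). So were those for S phase genes, of which 30 of 46 rose and 3 fell (camera adjusted p = 7.7e-07, and adjusted p = 0.069 with an estimated correlation; adjusted over the list alone, 30 rose and 4 fell). The same held for glycolysis genes, of which 10 of 25 rose and 1 fell (camera adjusted p = 0.00022, and adjusted p = 0.14 with an estimated correlation). It also held for NRF2 targets, of which 9 of 14 rose and 1 fell (camera adjusted p = 0.0072, and adjusted p = 0.078 with an estimated correlation; adjusted over the list alone, 9 rose and 2 fell). BAF subunits did not pass (adjusted p = 0.061) but did with the library set as a block (adjusted p = 0.046). With the length trend removed, MHC class II and immediate early genes passed with lower values at 72 h (adjusted p = 0.012 for each). For the memory B cell, immediate early and AHR target lists, which did not pass, the median, mean and test differed in sign. For 11 of 35 lists the counts changed when adjusted over the list alone, by at most 3 genes.

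The interaction test called 6894 genes between 24 and 72 h, 3661 with a higher and 3233 with a lower value at 72 h, 840 of them by at least 2-fold. With upper quartile scaling the share of higher calls was 41.4% in place of 53.1%. An F test over the 3 times called 7880 genes. Of 17 lists past camera, 13 passed with an estimated correlation.

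Within GFP high cells, the comparison of times shows what changed in the fraction as the experiment went on. VPREB1, part of the surrogate light chain of early B cells, rose from 1.27 ± 0.0534 CPM at 24 h to 2.98 ± 0.0386 at 48 h (1.23 ± 0.12, adjusted p = 8.82e-08), and GLRA3 rose by 1.34 ± 0.25. Small RNAs led the decreases to 48 h: RN7SKP9 (-1.64 ± 0.35), RNU4-1 (-1.58 ± 0.22) and RNU6ATAC (-1.54 ± 0.27) fell after MT-RNR1 (-2.42 ± 0.43) and MT-RNR2 (-2.02 ± 0.40). MT-RNR2 was at 0.65 ± 0.183 CPM at 24 h and its call was lost without library set 2 (-1.20, adjusted p = 0.058), while its value was -3.06 without the unnumbered GFP high library at 48 h. Between 24 and 48 h, 3388 genes passed the test, 1745 up and 1643 down. The share of calls up was 51.5%, against 44.6% with RLE size factors and 61.1% with upper quartile scaling. With the library set as a block 5394 passed, and 2195 with the unnumbered and set 1 libraries summed.

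By 72 h the chemokine CCL22 fell in GFP high cells from 17.9 ± 0.207 to 3.48 ± 0.538 CPM (-2.33 ± 0.07, adjusted p = 7.06e-16), as did the Fc receptor-like gene FCRL4 (-2.79 ± 0.19), the transcription factor BHLHE40 (-1.89 ± 0.12), AK8 (-1.78 ± 0.22) and the chemokine CCL5 (-1.71 ± 0.13). CHAC1, which breaks down glutathione and is induced when amino acids or folding capacity run short, rose from 4.9 ± 0.411 to 19.1 ± 0.624 CPM (1.96 ± 0.09), with INHBE (2.48 ± 0.12) and DBNDD1 (2.04 ± 0.13). MT-RNR2 (4.18 ± 0.23) and MT-RNR1 (4.14 ± 0.22) rose most, from the low levels given. In all, 4766 genes passed between 24 and 72 h, 2298 up and 2468 down, 294 by at least 2-fold.

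Within GFP low cells, several genes that were high at 24 h fell with time. CCR7 fell from 32.7 ± 1.5 CPM at 24 h to 10.9 ± 0.787 at 48 h and 3.63 ± 0.848 at 72 h (-1.58 ± 0.09 and -3.15 ± 0.10), and AHNAK changed by -1.73 ± 0.15 and -3.25 ± 0.17 as differences from 24 h. FCRL4 (-1.91 ± 0.15 and -4.05 ± 0.19) and CCL22 (-1.79 ± 0.06 and -3.17 ± 0.07) fell as well. JCHAIN rose from 280 ± 12.3 to 827.1 ± 24.8 CPM by 48 h (1.56 ± 0.04, adjusted p = 9.75e-19), and RPS3A (1.57 ± 0.02) and the mitochondrial dehydrogenase GPD2 (1.54 ± 0.15) rose with it. VPREB1 (1.91 ± 0.11 and 2.44 ± 0.11) and MLC1 (2.45 ± 0.19 and 2.89 ± 0.19) rose at both times, and DBNDD1 (2.87 ± 0.16), RNU6ATAC (2.62 ± 0.25) and CHAC1 (2.35 ± 0.09) by 72 h.

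MIR663AHG was among the genes that fell most in GFP low cells (-4.30 ± 0.86 and -3.42 ± 0.81), with 12.1 ± 18.3 CPM at 24 h. Without the unnumbered GFP low library at 24 h the values were -1.29 (adjusted p = 0.0006) and -0.42 (adjusted p = 0.2), and with limma-voom -2.77 (adjusted p = 0.062) and -1.75 (adjusted p = 0.16). Between 24 and 48 h 8373 genes passed in GFP low cells, 4241 up and 4132 down. Between 24 and 72 h 9403 passed, 4876 up and 4527 down, 1119 by at least 2-fold. Exon length was related to the change with time as follows: Spearman's rho across 10117 genes was -0.43 for 48 and for 72 h against 24 h in GFP low cells, and 0.3 and 0.06 in GFP high cells.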

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

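The test of S phase genes at 72 h was chosen only after the result had been seen, and matching on the length of the principal transcript was added after the matching on exon length had been seen. Splits that keep the library sets were added after the other splits had been seen. Effects that differed between times were picked out here, because the GFP low minus GFP high difference was measured at 3 times and its change was tested. Single libraries were not tested for standing apart within a group, since groups hold 3.

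The difference between GFP low and GFP high cells changed between 24 and 72 h for 6894 genes by the interaction test, and 718 of these were called in opposite directions at the 2 times. The F test over the 3 times called 7880 genes. Among lists, the median change of the difference was 1.54 for replication histones, 0.98 for mitochondrially encoded genes (0.63 with the length trend removed) and 0.70 for ribosomal protein genes. Among genes that the rule for named genes admits, the largest single changes upward were 2.75 for HBD, 2.64 for RNU6ATAC, 2.18 for RN7SKP203, 2.12 for RN7SL1 and 2.07 for RN7SKP71. Downward they were -4.51 for MT-RNR2, -3.87 for MT-RNR1, -3.81 for MIR663AHG, -2.02 for ATRN and -1.92 for ALPK2. The value of MIR663AHG was -0.81 (adjusted p = 0.068) without the unnumbered GFP low library at 24 h.

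Ribosomal protein, nuclear respiratory chain and replication histone genes, with median principal transcript lengths of 886, 1058.5 and 503 bp, were lower in GFP low cells at 24 h, where short genes were lower in general. The medians of the 3 lists differed by -0.54, -0.42 and -0.46 from those of random lists matched on exon length and by -0.29, -0.31 and -0.49 from those matched on the length of the principal transcript, each outside the central 95% of 10000 random lists, so length as the whole cause is argued against. For ribosomal protein genes, though, the matched median on principal transcript length was already -0.42 of the list's -0.71, so a length trend may account for part of the change. GC content does not carry the trend, as the lowest rho of fold change on exon length within 5 GC bands was 0.48. A change of the group itself with GFP level stays open as a hypothesis, with a ribosomal protein median of -0.58 once exon length and GC trends were removed. That correction used summed exon length, with a median of 3240 bp for these genes against 886 bp for the principal transcript. It may therefore remove too little of the trend for them. A difference in RNA integrity between the fractions at 24 h stays open too and was not tested.

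Replication histones rose in GFP low cells at 72 h after falling at 24 h. Length is argued against, because the list's median lay 0.43 above random lists matched on exon length and 0.43 above those matched on principal transcript length. More cells in S phase are argued against as well for these libraries, since the S phase list had a median of 0 at 72 h (95% interval -0.05 to 0.01). Of its 46 genes, 9 were up and 11 down. The 95% intervals in this paragraph come from 10000 resamplings of the genes of a list. They take the genes as independent and hold no spread between libraries or cultures. A larger share of RNA without a poly(A) tail in the GFP low libraries may account for the rise: 216 small nuclear, small nucleolar and Cajal body RNAs, which also lack the tail, had a median of 0.20 (95% interval 0.11 to 0.26), with 46 up and 3 down. At 48 h, where 31 of 41 histones rose with a median of 0.23, these small RNAs had a median of -0.19 (95% interval -0.24 to -0.08), with 6 up and 30 down, which goes against such a share at that time, while RN7SL1, which also lacks the tail, rose (1.00 ± 0.13), which goes with it; for 72 h the explanation stays open, beside a change of histone transcripts themselves with GFP level, which was not tested separately.

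Other splits of the same libraries were fitted. For the 7 comparisons of 3 against 3 libraries the 10 splits are too few to reach a share under 0.05. The real split was the 1 with as many calls in each, and the highest of the others called 0 genes, against 9531, 3926 and 4345 for GFP low against high at 24, 48 and 72 h. The real counts were 3388 and 4766 within GFP high cells and 8373 and 9403 within GFP low cells, for 48 and 72 h against 24 h. For the mean over times, 1 of 100 splits, the real one, reached 8550 genes and the highest other called 5148. For the F test over the times, 1 of 100 splits reached 7880 and the highest other called 5999. These splits exchanged libraries between the library sets, which pair them. Among 100 of the 256 splits that exchanged labels only within a set, the real one alone reached 8550 on the mean; the highest other called 7116 and differed in having all 6 libraries at 48 h exchanged. For the F test 3 of 100 such splits, drawn from 7776, reached 7880. The other 2 called 8087 and 8086 and differed in that 8 or 6 of the 9 GFP low libraries, and 0 of the GFP high ones, carried the label of another time, which brings the change with time into the tested difference. On the mean and for the F test, a share under 0.05 of the splits thus reached the real count. Splits that mix groups put the differences between groups into the spread within them, which lowers their counts. The result therefore says only that the groups differ among these libraries. It cannot exclude chance between cultures if the libraries of a group are repeats of 1 RNA sample. For the change between 24 and 72 h, 5 of 100 splits gave 6894 genes or more, the highest 8791, so chance cannot be excluded this way. The 4 splits above the real one called 8791, 7413, 6914 and 6905 genes. In them the labels 24 and 72 h were exchanged for 2 or 3 of the 3 libraries per time at 1 GFP level and for 0 or 1 at the other, which turns the interaction into the change with time itself, a structure of the samples. Of all 32 splits within the sets, 3 reached 6894, the highest again 8791, where all 6 GFP low libraries at 24 and 72 h were exchanged.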

How the results depend on the processing

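Chosen only after the data had been seen were the removal of length and GC trends, the block together with the length trend, the sum of the unnumbered and first libraries, the fit without library set 2 and the mean of 48 and 72 h. The cause of the changes given here was not tested, except where fewer libraries or a stricter threshold make it plain. The paired fit, with the library set as a block, called 10548, 5780 and 6043 genes at 24, 48 and 72 h, 9761 on the mean and 8349 for the change between 24 and 72 h, each within 1.5 times of the count without it. In GFP high cells from 24 to 48 h it called 5394 genes, or 5283 with the length trend removed too, while 2195 passed with the unnumbered and first libraries summed. Over 48 and 72 h alone 5361 genes passed, against 8550 on the mean of 3 times. Under the block 1731 genes were lower at both 24 and 48 h and 1601 at both 48 and 72 h. Among the lists and the single genes reported, the block changed no other call than those given. It did change how many members of a list were called. At 48 h 21 ribosomal protein genes rose and 30 fell under the block, against 2 and 14 without it. At 72 h 33 rose and 27 fell, against 13 and 15. At an adjusted p under 0.01, the shared genes were 691 higher and 759 lower for 24 and 48 h, 845 higher for 24 and 72 h, and 612 higher and 678 lower for 48 and 72 h.

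With an estimated correlation 10 lists passed at 24 h, 10 at 48 h and 14 on the mean. With fry, which sets no list against other genes, 33 passed at 24 h, 25 at 72 h and 32 for the change between the times. With length and GC trends removed, mitochondrially encoded genes turned on the mean, to a median of 0.03 (adjusted p = 0.55). Leaving out 1 library gave 8690 to 9110 genes at 24 h, 3120 to 3325 at 48 h, 3413 to 4019 at 72 h, 8222 to 8524 on the mean, 7355 to 7867 for the F test and 6463 to 6604 for the interaction. Within GFP high cells it gave 2640 to 2802 and 3793 to 4355 genes for 48 and 72 h against 24 h, and within GFP low cells 7683 to 7917 and 8621 to 8953. Lists past camera then numbered 16 to 17, 15 to 16 and 16 to 17 at the 3 times, 22 to 26 on the mean and 17 to 18 for the interaction. SMARCA4 ranged over 0.46 to 0.52, 0.10 to 0.14 and 0.17 to 0.22 at the 3 times and 0.26 to 0.29 on the mean, and BAF subunits called over 21 to 24, 6 to 8, 11 to 15 and 21 to 24. Of 268 values of single genes, all kept their direction and call with RLE and with upper quartile scaling, 265 did with limma-voom, and 2037 of 2040 did when 1 library was left out. Of 89 list calls, 89 stayed under the block, 76 with the length trend removed and 85 with the stricter filter. The median over genes shifted by at most 0.068 with another scaling. With upper quartile scaling the share of higher calls went from 50.7% to 59.4% at 24 h, and within a GFP level from 48.2% to 56.3% in GFP high cells at 72 h and from 50.7% to 45.5% and from 51.9% to 45.4% in GFP low cells at 48 and 72 h. Depth and spread limit small changes: of 50 simulated genes changed 1.25-fold at 24 h, 24 were recovered.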

Other observations

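The test of a difference between library sets was chosen only after the correlation of the sets had been seen. The lists of migration and adhesion genes, immediate early genes, and genes of the unfolded protein and integrated stress responses had members that moved in both directions, and none of the 3 passed camera at any time, except that immediate early genes were lower at 48 h once the length trend was removed (adjusted p = 0.029). Of 24 migration and adhesion genes, 9 rose and 11 fell at 24 h, 7 and 8 at 48 h and 6 and 10 at 72 h (camera adjusted p = 0.73, 0.1 and 0.97). RGS1, which dampens signalling from chemokine receptors, rose at each time (0.68 ± 0.03, 0.81 ± 0.03 and 0.70 ± 0.03), while the adhesion receptor CD48 fell (-1.15 ± 0.03, -0.31 ± 0.03 and -0.46 ± 0.03). Of 20 immediate early genes, 6 rose and 6 fell at 24 h, 1 and 6 at 48 h and 3 and 6 at 72 h (camera adjusted p = 0.3, 0.62 and 0.97). The ERK phosphatase DUSP5 rose (1.07 ± 0.04, 1.30 ± 0.04 and 1.10 ± 0.04), and EGR1 rose at 24 h (0.37 ± 0.06) and fell at 48 and 72 h (-0.43 ± 0.07 and -0.54 ± 0.06). Of 27 genes of the unfolded protein and integrated stress responses, 10 rose and 14 fell at 24 h, 5 and 9 at 48 h and 7 and 7 at 72 h (camera adjusted p = 0.21, 0.68 and 0.97). The chaperone HSP90B1 rose (0.28 ± 0.02, 0.21 ± 0.02 and 0.26 ± 0.02, with 0.07 at 24 h once the length trend was removed) and the chaperone HSPA5 fell (-0.29 ± 0.01, -0.24 ± 0.01 and -0.30 ± 0.01). Adjusted over the list alone, 7 migration genes rose at 72 h, 7 immediate early genes rose at 24 h and 7 fell at 72 h, and 6 stress response genes rose and 11 fell at 48 h.

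Targets of AHR, a receptor that indoles such as auxin can bind, did not move as a list: of 6 tested, 2 rose and 1 fell at 24 h, 2 fell at 48 h, and 1 rose and 2 fell at 72 h (camera adjusted p = 0.42, 0.24 and 0.59). Markers of epithelial, kidney and fibroblast cells did not pass either, with 3 of 4 up and 1 down at 24 h (camera adjusted p = 0.33), and VIM, an intermediate filament that lymphocytes also make, rose at 24 and 48 h (1.23 ± 0.16 and 0.95 ± 0.18). Of 3 myeloid markers only ITGAM passed at 24 h (1.74 ± 0.25; camera adjusted p = 0.42). Of 3 erythroid markers, 2 rose at 48 h and 1 at 72 h (camera adjusted p = 0.26 and 0.25), with the fetal haemoglobin chain HBG1 at 1.74 ± 0.42 and 1.74 ± 0.46. Adjusted over the list alone, 3 erythroid markers and 2 AHR targets rose at 72 h.

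The libraries of a group differed little. The sets may be repeated libraries of 1 RNA sample per group. If so, heat shock and immediate early genes, which change with handling, should vary no more than others. With the library set taken out, 32 such genes had a median variance 0.91 of that of expression-matched genes. That step removes handling differences between sets too, so 0.91 cannot tell repeats from separate cultures. The sets themselves differed: deviations from the group means correlated at 0.22 or more between libraries of the same set in different groups, and at 0.03 or less between sets. What the sets stand for is not given in the sources used here.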
